A study of Drosophila melanogaster with 5 samples.

How the data were processed

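Small RNAs of S2-NP cells were sequenced on an Illumina Genome Analyzer II in 5 libraries with 1 library per group, per the labels' protocols. Cells were soaked in 10 µg dsRNA per well in a pair of rounds 4 days apart and harvested 4 days after the second round, at 25 °C. RNA was extracted with Trizol and size-fractionated on polyacrylamide gels. The AGO1 and AGO2 immunoprecipitates came from evenly split extract of dcr-2 knockdown cells, with an anti-AGO1 and an anti-FLAG antibody. The mock library is marked as oxidized, and the sources used here do not say whether the knockdown libraries were oxidized.

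The values are read counts per distinct sequence as deposited by the authors, each with a sequence, a length and a name. The aligner, the mismatches allowed and the genome build behind the names are not given in the sources used here. The 3 whole-cell libraries and the 2 immunoprecipitates were named by different schemes. Between these sets 71.3% to 79.1% of shared sequences carried different names, and within a set 0%. Names were therefore harmonised by class, gene and transposon family, through the sequences that both sets share. Sequences without a name numbered 767 reads in mock, 917 in the ago1 knockdown, 926 in the ago2 knockdown, 15 in the AGO1 IP and 274 in the AGO2 IP, and stayed in the totals where 18 to 28 nt long.

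Reads of 18 to 28 nt, 97.2% to 99.7% of each library, were used and served as the total in place of genome-matching reads, since no genome sequence was at hand. For the same reason read strand, hairpin folds and reads matching a single genome position were not examined. Gene coordinates come from the BDGP6 annotation, and none are printed for the hairpin siRNA loci, whose names are not paired with annotated genes.

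miRNA arms were rebuilt from the sequences. The most abundant sequence of an arm was its reference, and a read was assigned to the arm when its 5' end lay within 2 nt of the reference's and the overlap was at least 15 nt. This gave 190 arms. Reads fitting several arms were shared among them. Guide strands followed a list fixed in advance, with 68 of 71 found, and the partner strand was the star. Arms were compared when at least 100 reads were summed over both libraries, and called at 2-fold. Arm counts were scaled to all miRNA-arm reads. Alternatives were scaling to all reads, TMM factors from edgeR and median-of-ratios size factors from DESeq2. Neither tool was used for a test. Arms without a read in 1 library were given as bounds against a floor of 3 molecules, and bounds that fixed no direction were left out. Star shares were compared for hairpins with at least 100 reads over both arms in each library, and called when exact binomial (Clopper-Pearson) intervals did not overlap. Pairing at nucleotides 9 and 10 was read from the RNAduplex structure of the dominant sequences of both arms.

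Lists were set against 10000 random lists of the same size matched in 5 abundance bins. The lists were guide strands, star strands, miR-2 and miR-13 family guides, mirtron arms and other-tissue miRNAs, fixed with the tests, comparisons, thresholds and naming rule before the data were examined. Named arms were the 8 largest ratios each way among arms with at least 200 summed reads, both arms of 12 preset hairpins (bantam, miR-184, miR-14, miR-277, miR-34, miR-276a, miR-8, miR-2b, miR-13b, miR-11, miR-33 and miR-305) and the 5 largest star-share differences each way. To these were added AGO1, AGO2, Dcr-2 and at most 5 hairpin loci and 5 transposons. List members, family members and genes beyond this rule were named after their values were seen.

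Choices made after the data were seen were the name harmonisation, the division of reads by copies per sequence for intervals and floors, the bounds left out, the use of RNAduplex, arms by deposited names, the totals without bantam-3p, without knockdown-target and virus reads and without other-tissue miRNAs, and the choice of arms whose lengths were examined. Intervals on folds are exact conditional intervals at 95%. Simulated libraries with known arm ratios were run through the same steps. Between 97.97% and 98.02% of simulated reads were assigned to an arm, whether or not it was their own. The simulation placed 98% of reads within the 2 nt allowed, so this value was set in advance. Of arms near 8-fold, 12 of 12 were called between the IPs, 5 of 5 for the ago1 knockdown and 2 of 2 for the ago2 knockdown against mock, and 12 of 12 between the knockdowns. Of arms near 4-fold the numbers in the same order were 8 of 9, 9 of 10, 33 of 33 and 10 of 10. Calls at 2-fold were also made on arms whose true change was under 1.4-fold, for 0 of 25, 2 of 5, 0 of 3 and 0 of 28 of them. Intervals on molecules held the true ratio for 98.25%, 96.88%, 100% and 91.04% of arms in those comparisons, and intervals on reads for 98.25%, 48.44%, 52.63% and 76.12%. Copies per sequence were simulated with the number that the intervals divide by, so that number was not itself checked. Star-share intervals held the true share in 95.25% of simulations, and 7 of 100 random lists fell in the outer 5% of percentiles.

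Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, ViennaRNA 2.7.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.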

Results

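Small RNAs were sequenced from S2-NP cells, a cultured Drosophila melanogaster line of the S2 family, in 5 libraries. Each library was the single member of its group. The groups were mock-treated cells (the one library whose title marks it as oxidized), cells soaked in double-stranded RNA (dsRNA) against ago1, cells soaked in dsRNA against ago2, and 2 immunoprecipitates (IPs) from an evenly split extract of dcr-2 knockdown cells, one of AGO1 and one of AGO2. AGO1 and AGO2 are the Argonaute proteins that hold microRNAs (miRNAs) and small interfering RNAs (siRNAs) in fly cells, and Dcr-2 is the Dicer that cuts long dsRNA into siRNAs. The series title names the rules of Argonaute loading as its subject. Libraries held 3802495 reads in mock, 1685130 in the ago1 knockdown, 2160073 in the ago2 knockdown, 5886369 in the AGO1 IP and 3819625 in the AGO2 IP.

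Loci and genes are given in reads scaled to 1000000 reads of 18 to 28 nt (RPM), and miRNA arms in reads scaled to 1000000 miRNA-arm reads (arm RPM). Each comparison sets 1 library against 1 other, so no difference has a replicate check and no p-value is given. Intervals are exact 95% intervals and cover counting error only, since reads amplified without molecular identifiers are not independent molecules. In mock, the most frequent number of reads per distinct sequence, leaving aside sequences read once, was 11, and 8.46% of sequences were read once. It was 3 in the ago2 knockdown. In the other 3 libraries the counts fell from 1 read onwards, so the number was taken as 1, and between 35.4% and 68.8% of sequences there were read once. Unless stated otherwise, intervals were therefore computed on reads divided by that number, and the floor was 3 such molecules, which is 33 reads in mock, 9 in the ago2 knockdown and 3 in the other libraries.

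**Figure D1:**
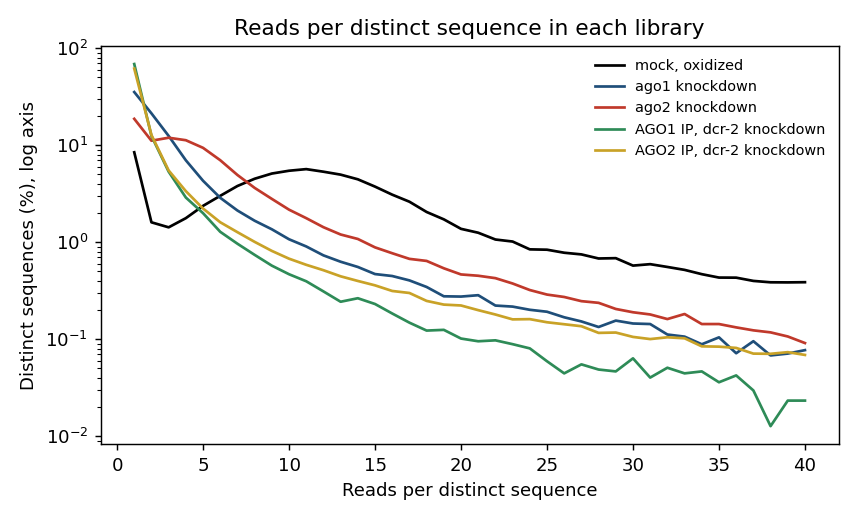
Percentage of distinct sequences (log axis) that were read a given number of times, from 1 to 40, with 1 line per library. Beyond sequences read once the mock line peaks at 11 reads per sequence, whereas the lines of the ago1 knockdown and of both IPs fall from 1 read onwards.

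Small RNAs matching the genes targeted by dsRNA were examined first, because dsRNA is diced into siRNAs of its own sequence and so marks the treatment. AGO1 (2R, 13943387 to 13958089) gave 288152 reads in the ago1 knockdown and 214 in mock, a 3114-fold difference relative to all reads (interval 2004 to 5138). AGO2 (3L, 15554113 to 15561042) gave 97587 reads in the ago2 knockdown and 1406 in mock, a 124-fold difference (104 to 148). Dcr-2 (2R, 17574979 to 17581525) gave 937831 reads in the AGO2 IP, 27103 in the AGO1 IP, and 20 in mock, 9 in the ago1 knockdown and 10 in the ago2 knockdown. Its differences from mock were 47148-fold in the AGO2 IP (12362 to 455398) and 876-fold in the AGO1 IP (230 to 8464), on a mock count below its floor of 33 reads. Both also set an IP against whole cells, and no whole-cell library of dcr-2 knockdown cells was made. The size of both is therefore uncertain and mixes the dsRNA treatment with the immunoprecipitation. Each target was thus highest in the libraries labelled with its knockdown. These reads report the dsRNA and not the level of the protein. Scaled to miRNA reads instead, the excess over mock was 302-fold for AGO1 in the ago1 knockdown, 12.1-fold for AGO2 in the ago2 knockdown and 20.4-fold for Dcr-2 in the AGO1 IP, the last on the same 20 mock reads.

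Other genes of the RNA interference pathway gave few reads. Dcr-1 had 26.7 RPM in mock (12.3 to 50.3) and at most 11.6 in the other libraries. In the AGO2 IP, r2d2 reached 154 RPM (142 to 168), and it had 36.9 in mock. For loqs the highest value was 282 RPM in the ago1 knockdown (257 to 309), with 121 in mock. Among genes with convergent overlapping transcripts, AGO2 and its neighbour CG7739 reached 6093 and 1846 RPM in the AGO2 IP, and 167 and 43.0 in the AGO1 IP. Another gene of that list, tkv, stayed between 0.683 and 28.2 RPM in every library.

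The small RNA classes were then compared. miRNAs made up 97.9% of reads in the AGO1 IP and 3.45% in the AGO2 IP, where transposon or repeat siRNAs (38.4%), Dcr-2 and AGO siRNAs from the knockdown class (25.5%) and siRNAs named after klar (24.6%) dominated. klar, which encodes the nuclear positioning protein Klarsicht, lies at 3L, 434083 to 540614, and is a rich source of siRNAs in these cells. Mock resembled the AGO2 IP more than the knockdowns did, with 2.28% miRNA, 49.0% transposon or repeat siRNA and 32.1% klar siRNA. miRNAs were 23.5% of reads in the ago1 knockdown and 23.3% in the ago2 knockdown. Oxidation leaves RNAs with a methylated 3' end, the form held by AGO2, more readily sequenced than others. Only the title of the mock library states oxidation, and whether the knockdown libraries were oxidized is not given in the sources used here, so every difference from mock carries that difference in labels.

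**Figure D2:**
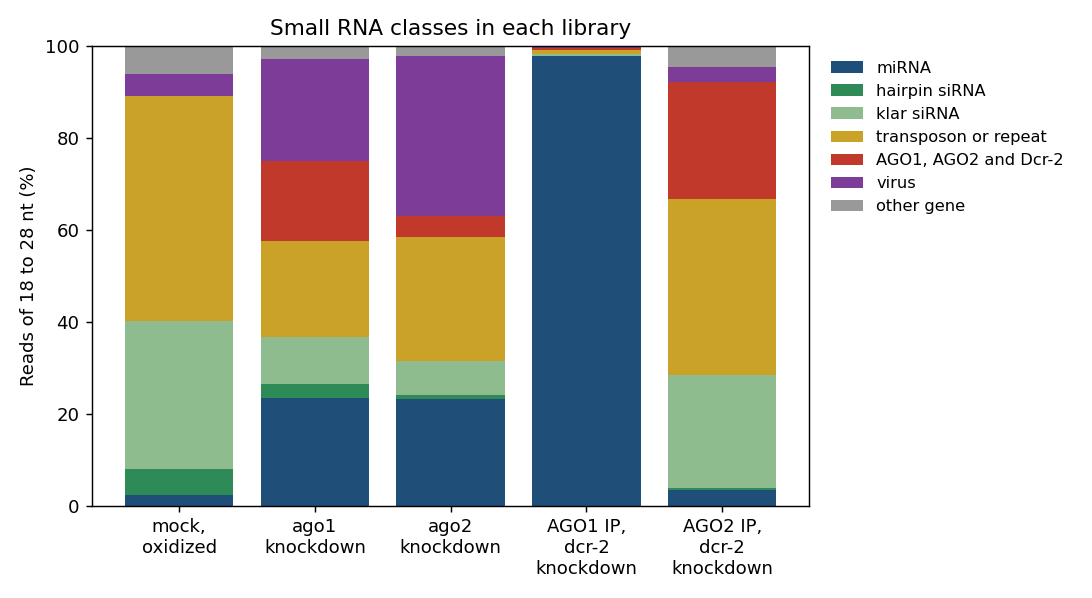
Percentage of reads of 18 to 28 nt in each small RNA class, stacked in 1 bar per library. miRNAs fill 97.9% of the AGO1 IP and 3.45% of the AGO2 IP, and virus siRNAs rise from 4.81% in mock to 34.8% in the ago2 knockdown.

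Shares of a class depend on what else the library held. Virus siRNAs made up 4.81% of mock, 22.1% of the ago1 knockdown and 34.8% of the ago2 knockdown, and the AGO1 dsRNA alone gave 17.6% of the ago1 knockdown. With virus and knockdown-target reads left out, a choice made after seeing the data, miRNA shares were 2.39% in mock, 38.9% in the ago1 knockdown and 38.4% in the ago2 knockdown. Counting error was small beside these differences; the interval of the miRNA share was 2.23% to 2.33% in mock and 23.2% to 23.4% in the ago2 knockdown. Among siRNAs, 21 nt was the most frequent length of the transposon, klar, virus and knockdown-target classes in all 5 libraries, with 75.9% of klar reads at 21 nt in the AGO2 IP and 59.7% in the AGO1 IP.

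The central comparison asked which miRNA strands were held by AGO2 and which by AGO1 when Dcr-2 was depleted. Star strands, the usually less abundant partners of the listed guide strands, were mostly enriched in the AGO2 IP. Roles came from the list, and some stars outnumbered their guides. In the AGO1 IP the star made up 86.8% of miR-308 and 74.7% of miR-277 reads. Of 17 star strands tested, 15 were at least 2-fold higher and 1 was at least 2-fold lower in the AGO2 IP, with a median log2 ratio of 4.96 (3.60 to 5.80). Guide strands, which usually accumulate and carry most miRNA function, split evenly, with 7 of 34 higher and 9 lower. Their median was 0.16 (-0.53 to 0.81) and was negative with the 3 other scalings. The star median was 3.54 with TMM factors and 3.19 with median-of-ratios factors, but 0.13 scaled to all reads, where its interval spans 0. The star median lay at percentile 100 and the guide median at percentile 12.3 of 10000 random lists of arms of like abundance. Star strands were 23.03% of miRNA-arm reads in the AGO2 IP and 0.367% in the AGO1 IP. Most of the AGO2 IP share came from 1 arm, the star shared by miR-276a and miR-276b, with 23028 of 129353 arm reads.

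Among arms with at least 200 reads over both IPs, the star strand shared by miR-276a and miR-276b had the highest ratio, at 178024 arm RPM in the AGO2 IP and 873 in the AGO1 IP, a 204-fold difference (198 to 210). Its hairpins lie at 3L, 10365228 to 10365325 and 10319785 to 10319883, in exons of long non-coding RNAs. miR-308-5p, from an intron of the ribosomal protein gene RpS23 (2R, 14215802 to 14215864), was 162-fold higher (139 to 191). miR-2a-2-5p and miR-2b-2-5p, from an intron of spi (2L, 19569490 to 19569561 and 19570182 to 19570264), were 55.7-fold and 31.0-fold higher. miR-184-5p was 94.5-fold higher on 133 and 62 reads, and miR-14-5p was 52.4-fold higher. miR-33-3p, from an intron of SREBP, was 45.6-fold higher, miR-275-5p 35.6-fold and miR-996-5p 28.97-fold. Scaled to all reads, miR-2a-2-5p (0.98), miR-14-5p (0.89), miR-33-3p (0.69), miR-275-5p (0.33), miR-2b-2-5p (0.13) and miR-996-5p (0.03) lay within 2-fold on the log2 scale. bantam-5p, the star of the growth-promoting miRNA bantam, was 15.8-fold higher (14.5 to 17.0), but scaled to all reads it was lower in the AGO2 IP, with a log2 ratio of -0.85.

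Several guide strands were lower in the AGO2 IP. miR-275-3p was 8.91-fold lower (7.71 to 10.4), miR-13b-3p 3.64-fold lower (3.34 to 3.97), miR-276a-3p 2.38-fold lower and bantam-3p 2.11-fold lower. miR-2c-3p and miR-307a-3p were 3.25-fold and 2.68-fold lower, each on 14 reads or fewer in the AGO2 IP. The miR-2c-3p counts were fractional, 739.3 and 5.167 in the AGO1 and AGO2 IPs, so they include reads shared with other arms. Their mean length in the AGO1 IP was 18.93 nt against a reference of 22 nt, so a change of miR-2c-3p itself was not shown. Outside the guide and star lists, miR-281-2-5p was 2.71-fold lower on 4 reads and miR-987-5p 4.31-fold lower on 9 reads. One star strand, miR-9b-3p, was 2.78-fold lower (1.46 to 6.09). The guide strands of the miR-2 and miR-13 seed family, which share targets among pro-apoptotic genes, had a median of -0.74. Of 5 guides none was above 0 and 2 were at least 2-fold lower, miR-13b-3p and miR-2c-3p with its shared reads. That median lay at percentile 24.5 of random lists, and was negative under every scaling. Some guides stood higher in the AGO2 IP: miR-33-5p by 6.11-fold, miR-277-3p by 2.99-fold and miR-184-3p by 2.22-fold, each of them lower scaled to all reads. With median-of-ratios factors miR-277-3p (-0.18) and miR-184-3p (-0.62) were lower too, and miR-184-3p was also lower with TMM factors (-0.27). Beyond the naming rule, miR-252-5p had the highest guide log2 ratio, 3.58, on 395 reads in the AGO2 IP and 1454 in the AGO1 IP. It stayed higher with TMM and median-of-ratios factors and was lower scaled to all reads. The log2 ratios of miR-34-5p (0.87), miR-8-3p (0.46), miR-14-3p (0.44), miR-305-5p (0.20), miR-305-3p (0.38), miR-11-3p (-0.42) and miR-2b-3p (-0.51) lay within 2-fold, and the positive ones among them were negative with the 3 other scalings. miR-8-5p and miR-277-5p were 4.05-fold and 2.01-fold higher, and scaled to all reads they were lower, miR-277-5p with TMM (-0.41) and median-of-ratios factors (-0.76) as well.

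Over all 58 arms with at least 100 reads, 25 were at least 2-fold higher and 12 at least 2-fold lower in the AGO2 IP. This split depended on the scaling. It was 17 higher and 25 lower with TMM factors, 16 and 29 with median-of-ratios factors (DESeq2), and 4 and 45 scaled to all reads. Against the main scaling these moved the median log2 ratio by -1.41, -1.77 and -4.83. The gap between the star and guide medians, 4.80 on the log2 scale, needs no scaling between libraries.

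The share of star reads within a hairpin also needs no scaling. It was higher in the AGO2 IP for 16 of 27 hairpins, lower for 2, and overlapped for 9, and the median share was 6.90% in the AGO2 IP and 0.368% in the AGO1 IP. In miR-988 the star made up 95.6% of reads in the AGO2 IP (91.4 to 98.1) and 8.33% in the AGO1 IP. For miR-14 the shares were 96.1% and 39.1%, for miR-276a 99.8% and 55.5%, for miR-996 39.98% and 1.12%, and for miR-275 38.4% and 0.196%. The share was lower in the AGO2 IP for miR-277 (66.4% against 74.7%) and for miR-9b (3.49% against 9.96%). Intervals overlapped for miR-995, miR-9c and miR-263a, which complete the 5 hairpins with the lowest differences.

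**Figure D3:**
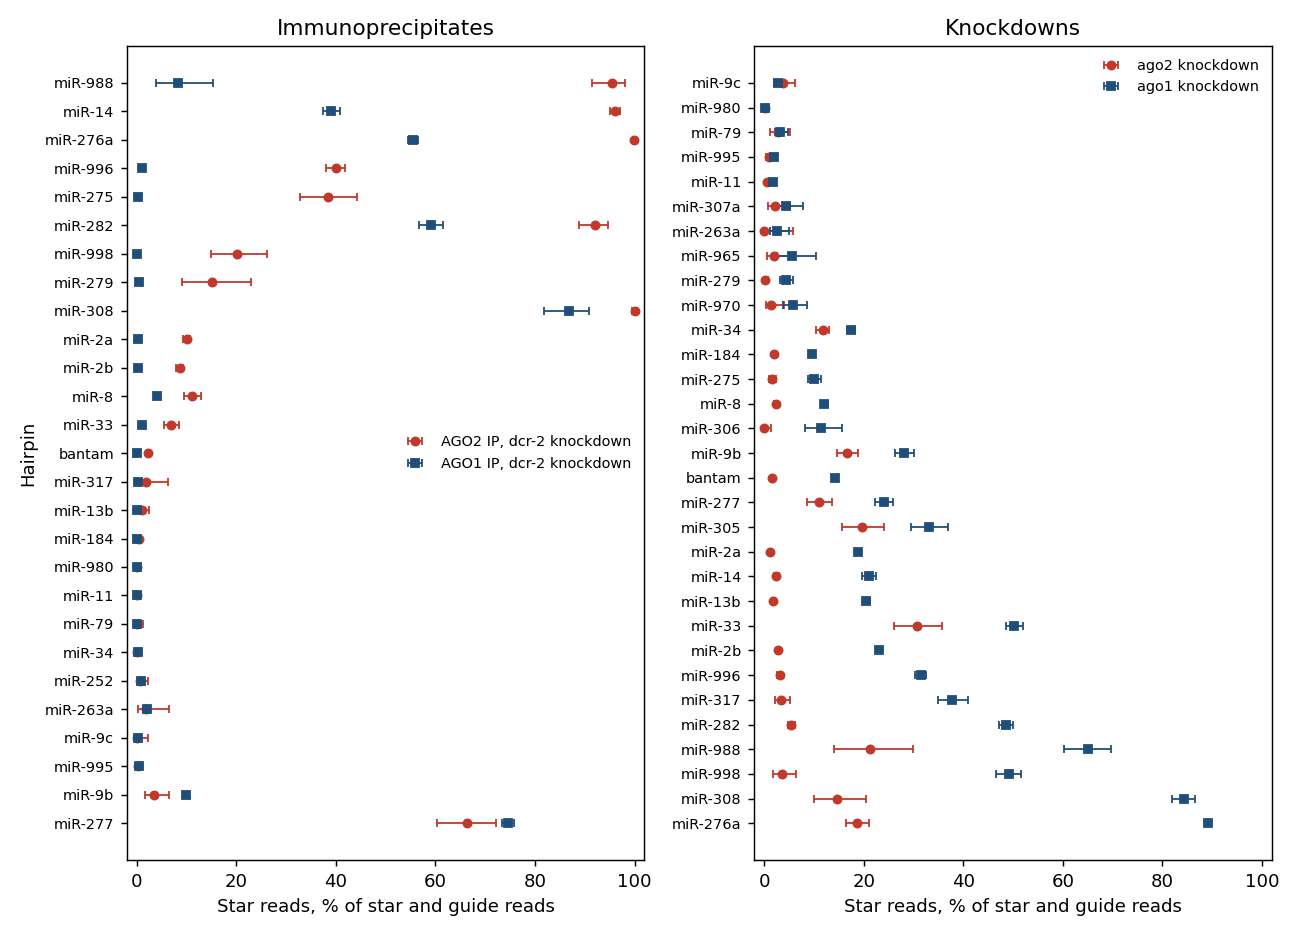
Star reads as a percentage of star and guide reads for each hairpin, with exact 95% intervals on reads divided by copies per sequence. In the left panel the AGO2 IP (circles) exceeds the AGO1 IP (squares) with intervals that do not overlap in 16 of 27 hairpins. In the right panel the ago2 knockdown (circles) lies below the ago1 knockdown (squares) with intervals that do not overlap in 23 of 31 hairpins.

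Sequence features of the strands were compared on the same ratios. Strands starting with C had a median log2 AGO2 IP over AGO1 IP ratio of 3.60 (1.00 to 5.80, 13 arms), and strands starting with U had -0.39 (-1.02 to 0.55, 34 arms). The U-first median lay at percentile 0.07 of random lists and the C-first median at percentile 95.9. Most C-first strands were stars, 10 of 13, and most U-first strands were guides, 27 of 34, so the base and the strand role were largely the same split. Strands starting with A had a median of 3.13 over 7 arms, and the 4 starting with G had 5.28. Strands with both nucleotides 9 and 10 paired in the duplex with their partner had a median of 1.37 (0.18 to 3.85, 34 arms), those with 1 paired 0.44 (13 arms), and those with neither paired -0.72 (6 arms). Among star strands alone the medians were 5.16 for both paired (13 arms) and 1.2 for 1 paired (4 arms), while among guides they were 0.20, 0.44 and -0.72 over 17, 9 and 6 arms. The both-paired median exceeded that of the other arms by 0.98, with a bootstrap interval from -0.15 to 3.65.

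Depletion of AGO1 was compared with mock next, where mock alone is marked as oxidized and the treatment of the knockdown RNA is not stated. The guide strands of bantam and of 3 of the 4 miR-2 and miR-13 family members tested were higher in the ago1 knockdown, and miRNAs known from tissues other than S2 cells were far lower. miR-2b-3p was 8.48-fold higher (6.97 to 10.4), miR-13b-3p 3.19-fold, miR-2a-3p 2.27-fold and bantam-3p 2.70-fold (2.54 to 2.88). Forms of 24 nt or more were 85.1% of miR-2b-3p in the ago1 knockdown and 37.9% in mock, so long forms carry much of its ratio. The last family guide tested, miR-11-3p, was 2.14-fold lower, though higher with TMM factors and scaled to all reads. Of the family's star strands miR-2a-2-5p was 8.25-fold lower, at 8024 arm RPM against 66161 in mock, with a log2 ratio of 0.32 scaled to all reads. The family median was 1.43, at percentile 92.9 of random lists. Of the other-tissue list all 4 testable members were lower, with a median of -7.36 (percentile 0.115). miR-1-3p, the muscle miRNA, was 222-fold lower (167 to 299), let-7-5p 121-fold and miR-318-3p 74.6-fold. miR-125-5p was 1478-fold lower (391.8 to 12482) on 2 reads in the ago1 knockdown, below its floor of 3, so the size is uncertain. All 4 reached the read minimum through mock alone, so their shared direction and the percentile were in part set by it. The whole list, with no minimum, was 5.57% of arm reads in mock and 0.0353% in the ago1 knockdown.

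Star strands did not move together in this comparison. Of 23 tested, 8 were at least 2-fold higher and 7 lower, with a median of 0.07 (-1.04 to 1.41, percentile 76.9), and of 41 guides 7 were higher and 18 lower, with a median of -0.44 (-1.82 to 0.14, percentile 39.6) that was positive with the 3 other scalings. Star strands of miR-34 (39.5-fold, 5.64 to 5176), miR-9b (10.1-fold), miR-13b-2 (8.57-fold), miR-277 (7.84-fold), miR-2b-2 (4.20-fold) and miR-14 (3.08-fold) were higher, where the mock counts behind miR-34, miR-9b and miR-277 were 8, 14 and 16 reads and below its floor. miR-11-5p had no read in mock and was at least 1.36-fold higher. miR-33-3p was 11.7-fold lower (10.5 to 13.1) and miR-33-5p 8.94-fold lower, but scaled to all reads their log2 ratios were -0.18 and 0.21. miR-263a-5p was 8.996-fold lower, miR-277-3p 3.52-fold, miR-8-3p 3.19-fold, miR-8-5p 2.11-fold, bantam-5p 2.05-fold and miR-305-3p 2.39-fold, and every one of these 6 was higher scaled to all reads, all but miR-263a-5p also with TMM factors, and bantam-5p also with median-of-ratios factors (0.001423). miR-989-3p was 194-fold lower, and miR-9a-5p, with no read in the ago1 knockdown, was at least 415-fold lower. miR-317-3p was 3.62-fold higher on 40 mock reads. miR-34-5p was 2.19-fold higher, an excess that came from forms of 24 nt or more, since with reads of 21 to 23 nt its log2 ratio was -0.076. Log2 ratios of miR-14-3p (0.99), miR-184-3p (0.12), miR-184-5p (0.07), miR-276a-3p (-0.34), miR-276a/b-5p (-0.51) and miR-305-5p (-0.98) lay within 2-fold, and the negative ones were positive with the 3 other scalings.

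In total 15 of 72 arms were at least 2-fold higher and 31 lower. The split was 43 higher and 15 lower with TMM factors, 32 and 20 with median-of-ratios factors, and 53 and 10 scaled to all reads, with median shifts of 2.06, 1.04 and 3.37. Free of scaling, the star share was higher in the ago1 knockdown for 13 of 28 hairpins and lower for 9 on intervals of reads, and for 6 and 6 on intervals of molecules. It rose from 1.16% to 17.5% in miR-34, from 4.11% to 28.2% in miR-9b, from 1.13% to 23.99% in miR-277 and from 8.76% to 20.5% in miR-13b. For miR-14 it was 20.96% against 14.6% in mock, with molecule intervals that overlapped. The star share fell from 75.4% to 18.8% in miR-2a, from 47.8% to 14.2% in bantam, from 91.3% to 65.0% in miR-988 and from 69.8% to 48.6% in miR-282, and in miR-308 it was 84.4% against 100% on 215 mock reads, with molecule intervals that overlapped.

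Depletion of AGO2 was compared with the same mock library, with the same gap in what is known of oxidation. Star strands were 2.33% of miRNA-arm reads in the ago2 knockdown, 18.2% in the ago1 knockdown and 32.7% in mock. Of 20 star strands tested against mock, 14 were at least 2-fold lower and 3 higher, with a median of -2.69 (-3.87 to -0.77, percentile 4.21), while 14 of 42 guides were higher and 17 lower, with a median of -0.43 (-2.04 to 0.95, percentile 97.8) that was positive with the 3 other scalings. miR-2a-2-5p was 140-fold lower (110 to 180), miR-998-5p, from an intron of E2f1, 84.6-fold, miR-33-3p 75.4-fold, miR-276a/b-5p 26.6-fold, miR-988-5p 25.5-fold and bantam-5p 14.6-fold, and these 6 were lower under every scaling. miR-8-5p (9.05-fold), miR-184-5p (8.33-fold) and miR-2b-2-5p (5.19-fold) were also lower, but scaled to all reads all 3 were higher than in mock. Scaled to all reads the star median itself was 0.98 over the arms testable on that scale.

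bantam-3p and 3 of the 4 tested guides of the miR-2 and miR-13 family were higher in the ago2 knockdown. bantam-3p was 4.06-fold higher (3.81 to 4.33), miR-2b-3p 4.04-fold, miR-2a-3p 3.72-fold, miR-13b-3p 3.71-fold, miR-14-3p 6.26-fold and miR-282-5p 5.03-fold. miR-11-3p, at -0.91, lay within 2-fold and turned positive with the other 3 scalings. The family median was 1.89, at percentile 67.9. miR-34-3p (17.4-fold), miR-9b-3p (7.68-fold) and miR-317-3p (8.62-fold) were higher on 8, 14 and 40 mock reads, and miR-306-5p, without a read in mock, was at least 4.08-fold higher. miR-33-5p was 25.4-fold lower, and miR-277-3p 4.91-fold, miR-305-3p 2.99-fold and miR-8-3p 2.33-fold lower, the last 3 being higher scaled to all reads, miR-305-3p and miR-8-3p also with TMM factors, and miR-8-3p also with median-of-ratios factors. The 4 other-tissue miRNAs were lower here too, with a median of -4.29 (percentile 4.52), of which miR-1-3p was 34.1-fold, miR-125-5p 382-fold, miR-318-3p 11.3-fold and let-7-5p 10.8-fold lower. miR-9a-5p was 44.6-fold lower. miR-277-5p was 2.19-fold higher on 16 mock reads, with an interval from 0.485 to 33.1, and log2 ratios of miR-34-5p (0.62), miR-276a-3p (0.59), miR-14-5p (-0.15), miR-305-5p (-0.27), miR-13b-2-5p (-0.52) and miR-184-3p (-0.58) lay within 2-fold, and the negative ones were positive with the 3 other scalings.

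Of 69 arms, 18 were at least 2-fold higher and 35 lower than in mock. The other scalings tested 71 arms. With TMM factors, median-of-ratios factors and all reads as the total the splits were 35 and 24, 29 and 26, and 43 and 12, and the median shifts 1.96, 1.52 and 3.36. The scale-free star share was lower in the ago2 knockdown for 17 of 27 hairpins and higher for 6, or for 14 and 2 on intervals of molecules. It fell from 75.4% to 1.23% in miR-2a, from 90.2% to 18.7% in miR-276a, from 91.3% to 21.2% in miR-988, from 69.8% to 5.44% in miR-282 and from 100% to 14.6% in miR-308. It rose from 1.16% to 11.7% in miR-34 and from 1.13% to 10.96% in miR-277. Shares of miR-9b, miR-9c and miR-79 were 16.6%, 3.77% and 2.74% in the ago2 knockdown and 4.11%, 0% and 0% in mock, with molecule intervals that overlapped; the 0 of 665 miR-9c reads allows up to 5.92% and the 0 of 660 miR-79 reads up to 5.96%.

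The knockdowns were finally set against each other, without the mock library. Of 49 listed star strands 23 reached the read minimum, and these were mostly lower in the ago2 than in the ago1 knockdown. Of the 23, 21 were at least 2-fold lower and none was above 0, with a median of -2.56 (-3.13 to -1.84) at percentile 0 of random lists. Below the minimum stars went both ways. In the ago2 and ago1 knockdowns miR-7-3p had 32.4 and 26.1 arm RPM, and miR-279-5p 8.10 and 112. Guide strands had a median of 0.59 (0.19 to 0.97) at percentile 99.97, with 12 of 37 higher and 4 lower. miR-998-5p was 34.2-fold lower (18.7 to 70.6), miR-2b-2-5p 21.8-fold (19.2 to 24.8), miR-276a/b-5p 18.6-fold (16.3 to 21.5), miR-2a-2-5p 17.0-fold, miR-308-5p 12.9-fold, miR-13b-2-5p 12.3-fold, miR-184-5p 8.75-fold, miR-317-5p 7.13-fold and bantam-5p 7.11-fold. All of these held under each scaling.

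Smaller falls were seen for the stars miR-33-3p (6.45-fold), miR-8-5p (4.29-fold), miR-277-5p (3.57-fold), miR-14-5p (3.42-fold), miR-11-5p (2.39-fold) and miR-34-3p (2.27-fold). With median-of-ratios factors miR-11-5p and miR-34-3p lay within 2-fold. miR-305-3p was at -0.32, or 0.16 with those factors. miR-9b-3p was at -0.39, or 0.09 with those factors. Higher in the ago2 knockdown were the guides miR-282-5p (4.06-fold), miR-14-3p (3.15-fold), miR-965-3p (2.88-fold), miR-308-3p (2.45-fold) and miR-996-3p (2.42-fold), together with miR-989-3p (14.01-fold). The 3 testable other-tissue miRNAs were also higher, with a median of 2.73 (percentile 97.7), among them miR-318-3p (6.61-fold) and miR-1-3p (6.52-fold). All 3 reached the read minimum through the ago2 knockdown alone, so their direction and the percentile were in part set by it. The whole list, with no minimum, was 0.223% of arm reads in the ago2 knockdown and 0.0353% in the ago1 knockdown. Of the guides, miR-33-5p was 2.84-fold lower and miR-2b-3p 2.098-fold lower, but with reads of 21 to 23 nt the log2 ratio of miR-2b-3p was 0.98. With median-of-ratios factors miR-2b-3p lay within 2-fold. bantam-3p (0.59), miR-276a-3p (0.94), miR-305-5p (0.71), miR-8-3p (0.46), miR-13b-3p (0.22), miR-11-3p (0.19), miR-277-3p (-0.48, or 0.002189 with median-of-ratios factors), miR-34-5p (-0.51) and miR-184-3p (-0.70) lay within 2-fold. The miR-2 and miR-13 family median was 0.22, at percentile 47.4, with 4 of 5 members above 0, among them miR-2c-3p with its shared reads.

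Counts over 66 arms were 13 higher and 25 lower, and 23 and 21 with median-of-ratios factors, which moved the median by 0.48. Star shares were lower in the ago2 knockdown for 25 of 31 hairpins and higher for none, or lower for 23 on intervals of molecules, with median shares of 2.41% and 17.5%. The share was 18.7% against 89.1% in miR-276a, 14.6% against 84.4% in miR-308, 3.58% against 49.1% in miR-998, 21.2% against 65.0% in miR-988 and 5.44% against 48.6% in miR-282. Differences above 0 were seen for miR-9c (3.77% against 2.76%) and miR-980 (0.216% against 0.201%), with overlapping intervals. By first base, C-first strands had a median of -1.82 (-2.83 to -0.32, 16 arms), U-first strands 0.59 (0.13 to 0.97, 38 arms), A-first strands -1.62 (6 arms) and G-first strands -2.20 (6 arms). By pairing at nucleotides 9 and 10 the medians were -0.98 for both paired (39 arms), -0.39 for 1 paired (15 arms) and 0.84 for neither paired (6 arms), and the difference between both-paired and other arms was -1.18 (-2.42 to 0.25).

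Strands enriched in the AGO2 IP were mostly those lower in the ago2 than in the ago1 knockdown. Across the 53 arms measured in both ratios, which share no library, Pearson's r was -0.82 (bootstrap interval over arms -0.90 to -0.75) and Spearman's rho -0.78 (-0.88 to -0.61). Both coefficients are the same under every scaling, whereas the counts that follow are not. Scaled to miRNA-arm reads, signs were opposite in 41 arms. On that scale 17 arms were at least 2-fold higher in the AGO2 IP and at least 2-fold lower in the ago2 knockdown, 4 were the reverse, and none passed 2-fold in the same direction in both. With TMM factors the same 2 counts were 15 and 5, and miR-2b-3p was at least 2-fold lower in both ratios. With median-of-ratios factors they were 14 and 15, with none in the same direction. Scaled to all reads they were 4 and 8, and 7 arms were at least 2-fold lower in both, among them miR-8-5p, miR-277-5p, miR-33-5p and miR-2b-3p. Within the 33 guides r was -0.58 and within the 17 stars -0.67. Arms are not independent replicates, so no p-value is attached.

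**Figure D4:**
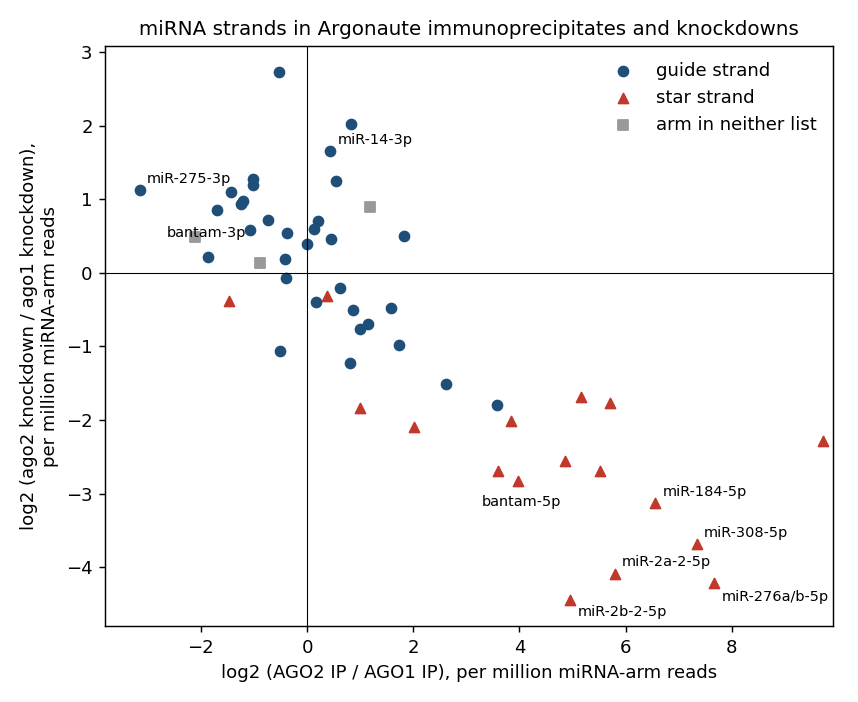
Log2 ratio of AGO2 IP to AGO1 IP (x axis) against log2 ratio of ago2 to ago1 knockdown (y axis), both scaled to miRNA-arm reads, for 53 miRNA arms. Star strands (triangles) lie mostly at the lower right, among them miR-276a/b-5p at 7.67 and -4.22, and guide strands (circles) around 0.

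Endogenous siRNAs of the 3 hairpin loci were compared in the same libraries. In the IPs, siRNAs of esi-1 had 2076 RPM in the AGO2 IP (2030 to 2122) and 175 in the AGO1 IP, those of esi-2 752 and 73.7, and those of esi-4 234 and 8.36. These values are scaled to all reads, so the miRNA reads that fill the AGO1 IP lower its side. On that scale klar siRNAs had 245807 and 4477 RPM, a larger contrast than at any of these loci. In the ago2 knockdown they were 2753, 4755 and 45.6 RPM, in the ago1 knockdown 7616, 21764 and 344, and in mock 11783, 44729 and 857. The single siRNA esi-2.1, the most abundant of them in the whole-cell libraries, fell from 21012 RPM in the ago1 knockdown (20790 to 21235) to 4485 in the ago2 knockdown (4331 to 4644). With virus and knockdown-target reads left out, the hairpin class was 4.93% of reads in the ago1 knockdown and 1.25% in the ago2 knockdown. Hairpin siRNA reads were 21 nt long for 65.1% in the AGO2 IP, 47.3% in the AGO1 IP, 44.95% in the ago2 and 30.5% in the ago1 knockdown. In the ago1 knockdown 60.8% were 22 nt long, so first bases at 21 nt cover unlike parts of these libraries. Of 21 nt hairpin siRNA reads, 44.2% began with C in the AGO2 IP and 23.03% in the AGO1 IP. In the ago2 knockdown 70.8% began with U, against 44.0% in the ago1 knockdown. Over distinct sequences, each counted once, these contrasts were much smaller, at 23.26% against 20.69% and 39.07% against 35.9%.

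Scaled to all reads, siRNAs of 5 transposons were higher in the AGO2 IP than in the AGO1 IP, and level or higher in the ago2 knockdown, where the hairpin siRNAs were lower. The retrotransposon 1731 had 131539 RPM in the AGO2 IP and 2977 in the AGO1 IP, mdg1 92461 and 2016, blood 36366 and 697, gypsy 19142 and 390, and 297 6586 and 192. This contrast depends on the miRNA reads that fill the AGO1 IP. With each distinct sequence counted once, the transposon or repeat class was 45.05% of the AGO2 IP and 51.8% of the AGO1 IP. The hairpin siRNA class was 0.521% and 0.903%, so both shares were higher in the AGO1 IP. Such shares ignore abundance, and counting once shrinks the miRNA class. In numbers the transposon or repeat class was larger in the AGO2 IP, with 1446685 reads against 48621 and 62412 distinct 21 nt sequences against 12237. Such numbers also depend on the miRNA reads that fill the AGO1 IP. Shares among reads other than miRNAs were not computed, so a preference of this class for AGO2 over other siRNA classes was not shown. In the ago2 and ago1 knockdowns, with virus and knockdown-target reads left out, 1731 had 99858 and 100769, mdg1 114589 and 83147, blood 50556 and 23984, gypsy 34499 and 21436, and 297 15073 and 11370 RPM. Other elements differed: INE-1 had 4109 and 6238 RPM and P 6102 and 7848, both lower in the ago2 knockdown. siRNAs of klar were 123814 and 171504 on the same scale. The transposon or repeat class as a whole was 44.3% of reads in the ago2 knockdown and 34.4% in the ago1 knockdown. Mock gave 180311 RPM for 1731 and 337189 for klar on that scale.

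Names of structural RNAs covered 221 reads of the AGO2 IP, 138 of the AGO1 IP and 0 in the other libraries, where such names were not used, so degradation there was not measured by them. Among reads named after other genes, 18 nt reads were 11.1% in the ago1 knockdown, 7.70% in the ago2 knockdown and 0.479% in mock. Reads of 24 to 28 nt starting with U and outside miRNAs were 0.238% of mock, 0.149% of the ago1 knockdown, 0.298% of the ago2 knockdown, 0.0119% of the AGO1 IP and 0.0150% of the AGO2 IP. Mirtron arms, cut from short introns, had between 59 and 498 reads per library and at most 2 passed the read minimum in any comparison, so no list median was computed.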

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

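The tests weighed elsewhere in the closing section were all chosen after the results were seen, and none was run for the values given here. No biological explanation was tested for them.

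Reads named after lacZ lay outside every comparison. They reached 609 RPM in the AGO2 IP (584 to 635), 9.896 in the AGO1 IP and 4.27 in the ago1 knockdown, the last from 7 reads. None were seen in mock or the ago2 knockdown, which allows up to 0.00107% and 0.000520% of reads. The labels do not mention lacZ.

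Star shares of 2 hairpins, miR-13b and miR-8, moved in opposite directions in the knockdowns against the shared mock library, on intervals of molecules. The share of miR-14 did so on intervals of reads alone, with differences of 6.36 and -12.2 points. In miR-13b the star share rose by 11.8 percentage points in the ago1 knockdown, and the difference was -6.98 points in the ago2 knockdown. In miR-8 the differences were 3.73 and -6.04 points. Each effect rests on 1 library against the same mock library, and the difference between the effects was not tested against mock. Between the knockdowns themselves, the ago2 minus ago1 difference was -18.7 points in miR-13b and -9.77 points in miR-8.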

How the results depend on the processing

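Arms by deposited names, totals without bantam-3p, intervals on reads divided by copies per sequence, and totals without knockdown-target and virus reads or without other-tissue miRNAs were chosen after the results were seen. No paired analysis was possible because each group held 1 library. Of 1714 recomputed log2 ratios of named arms 1281 kept their value within counting error, 395 moved, and 38 that were past 2-fold in the main analysis changed sign. With ratios inside 2-fold included, 99 changed sign, of which 33 scaled to all reads, 23 with TMM factors and 20 with median-of-ratios factors. Of 191 list medians 131 kept their value, 59 moved, and 1 that was past 2-fold changed sign. Kept here means inside the interval of the main median, or close to that median where no interval was computed. With medians inside 2-fold included 19 changed sign, of which 4, 3 and 3 under those scalings, among them the guide medians of the IPs and of both comparisons with mock. Of 413 counts, shares, differences and correlations 278 were kept and 135 moved. A count was kept within a set factor, which took 25 and 17 arms as alike but not 12 and 25. Other values were kept when inside their main interval. Matching of 5' ends exactly or within 5 nt, 1 mismatch, dropped ambiguous reads, 20 reads over both arms, and totals without other-tissue miRNAs changed the sign of no value past 2-fold. The counts of called arms and hairpins, median differences and correlations stayed within these tolerances there. Among single ratios, exact matching of 5' ends moved 7 of 131 and changed the sign of 2 inside 2-fold and of 1 list median, the guide median of the IPs. Reads matching 1 genome position were not run, for lack of a genome sequence.

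Scaled to all reads instead of miRNA-arm reads, AGO2 IP against AGO1 IP gave 4 arms higher and 45 lower, and ratios of -0.85 for bantam-5p, -3.68 for miR-184-3p, -3.24 for miR-277-3p, -3.82 for miR-277-5p, -2.22 for miR-33-5p and -2.81 for miR-8-5p. For ago1 knockdown against mock it gave 53 higher and 10 lower, and 2.33 for bantam-5p, 2.27 for miR-11-3p, 0.20 for miR-263a-5p, 1.55 for miR-277-3p, 2.11 for miR-305-3p, 0.21 for miR-33-5p, 1.69 for miR-8-3p and 2.29 for miR-8-5p. For ago2 knockdown against mock it gave 43 higher and 12 lower, 0.30 for miR-184-5p, 1.06 for miR-277-3p, 0.98 for miR-2b-2-5p, 1.78 for miR-305-3p, 2.14 for miR-8-3p, 0.18 for miR-8-5p, and a star median of 0.98. By construction these follow the miRNA share of the libraries.

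TMM factors gave 25 arms lower in the AGO2 IP, with miR-184-3p at -0.27 and miR-277-5p at -0.41. For ago1 knockdown against mock they gave 43 higher and 15 lower, with bantam-5p at 1.02, miR-11-3p at 0.96, miR-277-3p at 0.24, miR-305-3p at 0.80, miR-8-3p at 0.38 and miR-8-5p at 0.98. For ago2 knockdown against mock they gave 35 higher, miR-305-3p at 0.38 and miR-8-3p at 0.74. Median-of-ratios factors gave 16 higher and 29 lower between the IPs, with miR-184-3p at -0.62, miR-277-3p at -0.18 and miR-277-5p at -0.76. They gave 32 higher and 20 lower for ago1 knockdown against mock, with bantam-5p at 0.001423. They gave 29 higher for ago2 knockdown against mock, with miR-8-3p at 0.30, and 23 higher for ago2 against ago1 knockdown. Totals without bantam-3p gave 20 arms lower in the AGO2 IP and 20 higher in the ago2 against the ago1 knockdown. The cause was not tested.

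A minimum of 10 reads, which tests more arms, gave 50 arms higher in the AGO2 IP, 58 lower in the ago1 knockdown and 64 lower in the ago2 knockdown against mock, 36 higher in the ago2 against the ago1 knockdown, and r of -0.66 between the IP and knockdown ratios. With at least 1 read in each library the values were 64, 54, 65 and 32 arms, r of -0.57 and rho of -0.58. A minimum of 1000 reads, which tests fewer, gave 14 higher in the AGO2 IP, 14 lower in the ago1 knockdown against mock, 11 higher and 15 lower in the ago2 knockdown against mock with a star minus guide median of -4.47, and 6 higher and 15 lower in the ago2 against the ago1 knockdown.

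With reads of 21 to 23 nt, miR-34-5p was at -0.076 in the ago1 knockdown against mock and miR-2b-3p at 0.98 in the ago2 against the ago1 knockdown, as forms of 24 nt or more were left out, and 1 hairpin had a lower star share in the AGO2 IP. By deposited names miR-34-5p was at -0.17 in the ago1 knockdown against mock. Its ratio in the ago2 against the ago1 knockdown, inside 2-fold, also changed sign under both of these settings. With at least 1000 reads over both arms, fewer hairpins were compared. Star shares were then higher for 9 and lower for 0 in the AGO2 IP, higher for 4 in the ago1 knockdown against mock, and higher for 2 and lower for 9 in the ago2 knockdown against mock. Intervals on reads divided by copies per sequence gave 6 hairpins higher in the ago1 and 2 in the ago2 knockdown against mock. The cause was not tested beyond the numbers compared.

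miRNA shares in mock, the ago1 knockdown, the ago2 knockdown, the AGO1 IP and the AGO2 IP were 0.633%, 4.73%, 5.002%, 84.5% and 0.385% of 21 nt reads, and 0.341%, 0.592%, 0.487%, 2.71% and 0.212% of distinct sequences. Without knockdown-target and virus reads they were 2.39%, 38.9%, 38.4%, 98.5% and 4.84%. Transposon or repeat shares in the same order were 52.4%, 27.9%, 33.7%, 6.67% and 40.45% of 21 nt reads, and 55.6%, 47.2%, 50.6%, 51.8% and 45.05% of distinct sequences. Without knockdown-target and virus reads they were 51.5%, 34.4%, 44.3% and 53.8% in mock, the knockdowns and the AGO2 IP. Relative to miRNA-arm reads the excess over mock was 302-fold for AGO1 in the ago1 knockdown, 12.1-fold for AGO2 in the ago2 knockdown and 20.4-fold for Dcr-2 in the AGO1 IP. The last rests on 20 mock reads, below its floor of 33, and sets an IP against whole cells. Depth limits the mock library, whose 85851 arm reads stand for fewer molecules, and the AGO2 IP, where several guides rest on under 20 reads.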

Other observations

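Tests of the 3 patterns weighed here were chosen only after the results were seen. Among viruses, RNA1 and RNA2 of Flock House virus gave 33903 and 13319 RPM in mock, 66745 and 153770 in the ago1 knockdown, 107093 and 239744 in the ago2 knockdown, 11677 and 20171 in the AGO2 IP, and 289 and 1407 in the AGO1 IP. Reads of Drosophila C virus stood at 502 RPM in mock, 568 in the ago1 knockdown, 389 in the ago2 knockdown, 13.3 in the AGO2 IP and 0.341 in the AGO1 IP. Cricket paralysis virus had 359, 400 and 312 RPM in mock and the ago1 and ago2 knockdowns. At 21 nt lay 74.85% to 78.62% of Flock House virus RNA1 reads in whole cells but 22.95% to 48% of Drosophila C virus reads.

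miRNAs of other tissues made up 5.57% of arm reads in mock and at most 0.223% in the other libraries. Their reads scaled to all reads were 2.44 times as high in mock as in the ago2 knockdown (2.12 to 2.81), which argues against the low miRNA share of mock as the whole cause. That total includes virus and knockdown-target reads, a larger part of the ago2 knockdown than of mock, and the ratio without them was not computed. Of the 4784 list reads in mock, 2989 were miR-1-3p. Retention in AGO2 stays open. The summed AGO2 to AGO1 IP ratio was 0.856 (0.408 to 1.59) on 10 and 515 reads, of which miR-318-3p gave 8 and 508. miR-1-3p had 1 and 2 reads, let-7-5p 1 and 5, and miR-125-5p 0 and 0. The ratio is thus almost wholly that of miR-318-3p and cannot decide for the others, which were nearly absent from both IPs. Reads carried over from other tissues may be a source, as 4 of 5 tissue groups had a member above the floor, but only 6 of 15 members did. Long U-first reads of 24 to 28 nt were taken as a second sign of this source, if higher in mock than in both knockdowns. They were 0.238% in mock, 0.149% in the ago1 and 0.298% in the ago2 knockdown, so that condition failed. It was not shown that each tissue group of the list would bring such reads. The failure therefore counts neither for nor against this source, which was not decided. Oxidation, which the labels give to mock alone, was not tested.

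Forms of 24 nt or more were 64.3% of miR-34-5p in the ago1 knockdown, 24.4% in the ago2 knockdown and 11.9% in mock, and 85.1%, 33.6% and 37.9% of miR-2b-3p. To weigh different size selection, the odds ratio of such forms was pooled over 24 other arms. It was 1.07 (1.03 to 1.11), beside 5.57, 11.3 and 4.03 for miR-34-5p, miR-2b-3p and miR-263a-5p. The pool leans on arms with many long forms, such as miR-2a-3p with 42.56% in the ago1 knockdown and 1.115 alone (1.066 to 1.166). The other arms did not move alike: of 17 with an odds ratio of their own, 5 had intervals above 1, among them miR-305-5p at 6.51 (3.99 to 10.6) and miR-317-3p at 1.91, and 5 had intervals below 1, among them miR-13b-3p at 0.424 (0.349 to 0.515) and bantam-3p at 0.809. Only 8 of the 17 had an upper bound below the lowest bound of the 3 arms. Longer forms were thus not confined to the 3 arms picked. The arms below 1 argue against a size selection that raised every arm alike, but the pooled value cannot exclude size selection as a part of the cause. Retention of the long forms in AGO2 was weighed by their share in the IPs, which come from dcr-2 knockdown cells. The AGO2 minus AGO1 IP difference was -17.7 points for miR-34-5p and -34.9 for miR-263a-5p, the latter on 106 AGO2 IP reads. It was 21.9 points for miR-2b-3p. In those cells the values argue against enrichment of the long forms in AGO2 for miR-34-5p and miR-263a-5p, but not for miR-2b-3p. What AGO2 holds when AGO1 is depleted was not measured, so retention in the ago1 knockdown was not decided. Less trimming when AGO1 is depleted may be a cause, as long forms of miR-34-5p were 3.75 times as high in the ago1 as in the ago2 knockdown (3.41 to 4.12) and shorter forms 1.49 times as high in the ago2 knockdown. This is a hypothesis found and tested on the same libraries.

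siRNAs named after pyd, dnt and CG17684 in the whole-cell libraries numbered 282824, 73945 and 33113 reads in mock. At least 99.94% of their sequences found in the IPs carried a transposon name there, led by 1731, blood and 3S18. Reads shared with transposons are thus a candidate source of these gene names, and no biological explanation was tested. klar differed, with 0.0296% of 20270 shared sequences carrying a transposon name.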
